A study of Mus musculus with 6 samples.

How the data were processed

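RNA had been extracted with Trizol from GFP+ HSCs sorted from the bone marrow of C57BL/6J mice, and libraries had been made with an mRNA kit (VAHTS mRNA-seq V3), per the labels. There were 6 libraries, 3 from recipients of HSCs given a control RNA and 3 from recipients of HSCs given a miR-31-5p inhibitor. The replicate numbers in the titles are not said to pair a control with an inhibitor library. The deposited values of each library were read counts per RefSeq gene symbol, 25033 in all, summed by the authors over the transcripts of a symbol and not normalised. The genome build was mm10 and bcl2fastq 2.20 was used, per the submitters' processing notes. The aligner, the counting tool and the strand of counting are not given in the sources used here, so reads of antisense or overlapping genes cannot be told apart. A second deposited column held RPKM values per the file headers, that is, counts divided by the longest transcript length and by a library total. It was used only to check the counts: the library totals implied by RPKM exceeded the summed counts by 2.82, 0.49 and 8.68% in control libraries 1 to 3 and by 0.22 to 0.35% in the inhibitor libraries. The list of genes held 0 columns of samples of other series. Mitochondrially encoded genes and Mir31hg were not analysed here.

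Each library was its own sample, and the inhibitor group was compared with the control group. Libraries held 16873188 to 21245861 counts, so that 3 counts corresponded to 0.141 to 0.178 CPM, and the 50 most abundant genes took 10.3 to 11% of the counts. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12978. Counts were scaled by TMM (factors 0.985 to 1.008) and tested with edgeR 4.0.16's robust quasi-likelihood test in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Replicates were compared by a chi-square over genes with at least 20 counts. Levels are TMM-normalised CPM, given as mean ± SD. The principal components used log2 CPM with a prior count of 2.

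Gene lists, written from general knowledge before the data were examined, numbered 37, and 35 had at least 5 tested genes. The list of mitochondrially encoded genes had none and the sex chromosome list had 4, which are reported singly. List members with no listed symbol were left out. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and as alternatives with an estimated correlation and with fry. Genes named in the text followed a rule that was also set before the data were examined. It took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 10 counts over the libraries and groups that did not overlap. Predicted genes and pseudogenes were to be left out of these, and 0 were met. It also took the 4 members with the smallest p-values of each list past the threshold and up to 2 members past the threshold of each other list. Among the genes fixed in advance were Mir31, Hif1an, Lats2, Satb1, Dicer1, Rhobtb1, Procr, Mecom, Hlf, Kit, Slamf1, Cd34 and Flt3. The text prints most of these genes and leaves out others, some of which are not reported here. Genes from outside this rule are said to have been chosen after their values were seen.

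Sites of the miR-31-5p seed (TCTTGCC, or TCTTGCCA for the 8mer) were sought in the longest annotated 3′ UTR of each gene in GENCODE release M21. Of the deposited genes, 24264 were matched to that annotation by accession, 435 by symbol and 334 not at all. Gene coordinates are those of RefSeq on mm10. The difference in median log2 change was given a bootstrap interval over 2000 resamples of genes, and was set against the 7-letter permutations of the site found in a like number of genes. Python 3.11.15 was used for the sequence search.

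The procedure was tested on simulated data, in which 200 of 12978 genes were changed, 50 each by 1.25-, 1.5-, 2- and 4-fold. Of these, 21, 39, 45 and 48 were recovered, and 15 unchanged genes were called (8.9% of calls). A planted list of 40 genes changed by 1.25-fold passed with both correlations. The simulated genes varied independently of each other, so this says nothing of lists whose genes move together. Alternatives fixed before the data were examined were RLE size factors, no filter and a stricter filter on low counts (1 CPM in all libraries of a group and a mean of 10 counts), the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma-voom, an adjusted p of 0.1, a minimum log2 change of 1, 8mer sites alone and all annotated 3′ UTRs. Chosen after seeing the data were a loess correction for GC content and transcript length in each library (span 0.4), thinning every library to the smallest total, leaving out Rn45s with the 50 most abundant genes, leaving out control libraries 1 and 3 together, and leaving out list members shared with other lists. Also chosen then were 4 further lists, given at the end of the document, and 10000 random lists matched for GC content, length and level.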

Results

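Cells derived from transplanted haematopoietic stem cells (HSCs), the marrow cells from which all blood lineages arise, were profiled by RNA sequencing. Donor HSCs had been treated with a control RNA or with an inhibitor of miR-31-5p, a microRNA that represses transcripts holding a match to its seed. Green fluorescent cells were later sorted from the recipients' marrow. The series held 3 control and 3 inhibitor libraries from C57BL/6J mice of 6 months. Total counts were 20222053, 19866738 and 21245861 in control libraries 1 to 3, and 19496200, 17101645 and 16873188 in inhibitor libraries 1 to 3. Of 25033 gene symbols listed, 7598 had a count in no library and 12978 were tested. Pairs of libraries of the same group differed by more than counting noise, with a chi-square per degree of freedom of 7.55 to 16.78 among controls and 3.04 to 4.24 among inhibitor libraries. Each was therefore used as a replicate. Pairs from different groups gave 36.15 to 55.75, and the first principal component, with 70.8% of the variance, separated the groups. Control library 1 stood apart from the other controls on the second component, which held 9.5%. The precursor ribosomal RNA gene Rn45s, chosen after its values were seen, also varied, with 20039, 3667 and 61656 counts in control libraries 1 to 3 and 1784 to 3145 in the inhibitor libraries. The 4 tested sex chromosome genes (Ddx3y, Eif2s3y, Kdm5d and Uty) had log2 changes between -0.03 and 0.04, with an adjusted p of at least 0.673 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nothing in the labels says that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. Mir31, the precursor gene of the targeted microRNA (mm10 chromosome 4, 88910557 to 88910662), had a count of 0 in all 6 libraries, so its level was under 0.141 to 0.178 CPM (counts scaled to library size), taking 3 counts per library as the limit. An mRNA library is not made to capture a mature microRNA, so these counts give no measure of the inhibition. Counting intervals and floors here cover counting error only.

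The comparison asked which transcripts differ in HSC-derived GFP+ cells when the transplanted cells had received the miR-31-5p inhibitor and not the control RNA. In the inhibitor group, genes of megakaryocytes and platelets, genes known to rise in aged HSCs and p53 response genes were higher. Genes of cholesterol synthesis and of the G1/S transition and DNA replication were lower. Thbs1, which encodes the platelet granule protein thrombospondin 1 (chromosome 2, 118111876 to 118127133), rose from 123.5 ± 7.31 to 621.6 ± 12.2 CPM (mean ± SD, n = 3 libraries per group). This was a 5.03-fold rise, or 2.33 ± 0.06 on the log2 scale (± SE), with an adjusted p = 3.75e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Hmgcs1, the cytosolic HMG-CoA synthase (chromosome 13, 119690351 to 119708260), went from 236.8 ± 2.29 to 98.7 ± 1.56 CPM, a log2 change of -1.26 ± 0.05 (adjusted p = 5.96e-11 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In all, 5259 of the 12978 tested genes (40.5%) passed an adjusted p of 0.05, 2646 of them higher and 2613 lower in the inhibitor group. At least 2-fold changes were seen in 853 of these genes, 697 higher and 156 lower. All changes below are log2 changes of inhibitor against control with their SE, unless a fold or level is named. In 6805 of all 12978 tested genes (52.4%), the 3 inhibitor libraries lay on one side of the 3 control libraries, which chance gives for 10% of genes. Camera called 19 of the 35 gene lists that were tested, 13 higher and 6 lower, with its preset correlation between genes, and 5 of them with an estimated correlation. Those 5 are the groups named at the start of this paragraph. The preset correlation also called 8 to 16 lists when the 6 libraries were parted into 3 and 3 in the other 9 ways.

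**Figure D1:**
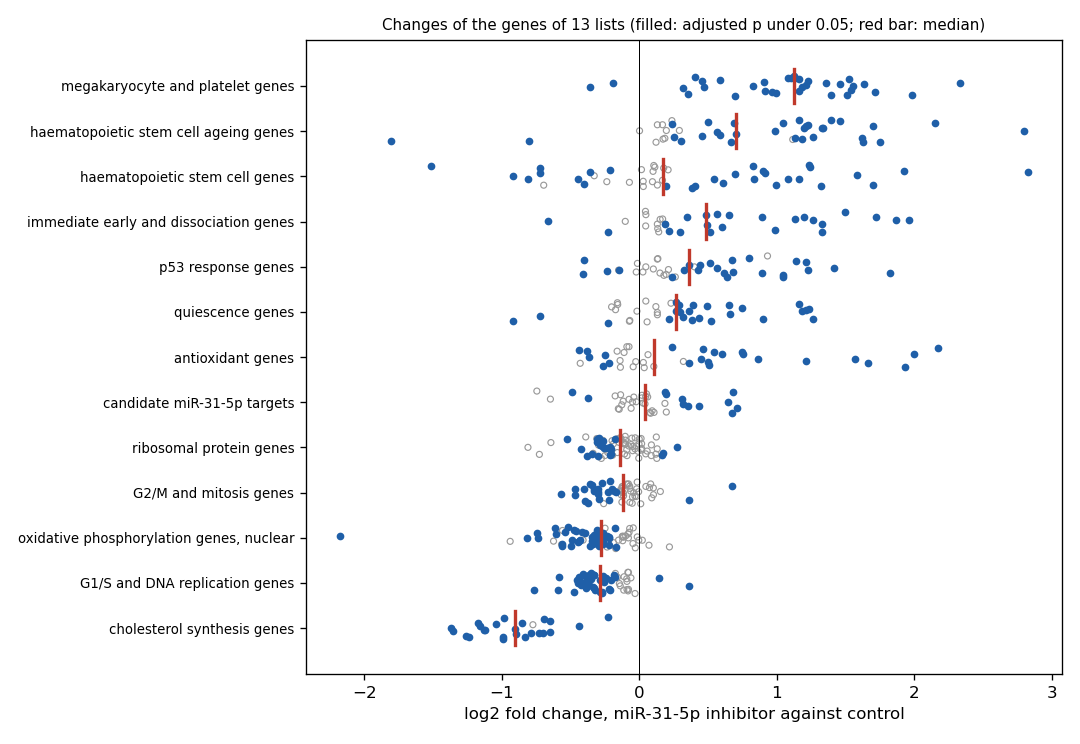
Log2 changes (horizontal axis) of the tested genes of 13 lists, inhibitor against control, with 1 point per gene, filled where the adjusted p is under 0.05, and a red bar at each list's median. The megakaryocyte and platelet list has the highest median, 1.13, and the cholesterol synthesis list the lowest, -0.90.

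The largest rises past the threshold were in genes with few reads in the control group, so they are given as ratios of counts scaled by library size, with 95% counting intervals. Hba-a2, an alpha globin gene, went from 8 counts over the 3 control libraries to 301 over the inhibitor libraries, a ratio of 43 (21.5 to 101). Hba-a2 and Hba-a1 are near-identical, so the split of reads between them is uncertain. Sorcs1 (3 counts against 90, ratio 34.3, 11.4 to 169) and Csn2, which encodes beta casein (2 against 58, ratio 33.1, 8.77 to 280), followed. Gli3, a transcription factor of Hedgehog signalling, had 24 counts against 356, a ratio of 17 (11.2 to 26.8). The ratios of Cspg4 and Scube1 were 23.1 (11.9 to 51.4) and 22.9 (11.3 to 53.9), and those of Myl9, Gsta3 and Mmp13 16.6 (8.14 to 39.3), 16.2 (8.57 to 34.6) and 16.9 (6.25 to 63.9). Eps8l2 had a ratio of 23.6 (7.72 to 118), with all 3 of its control counts in control library 2. Several of these ratios leaned on 1 library. Without control library 1, Cspg4 had a ratio of 70.2 (19.1 to 584) and Scube1 41.1 (13.8 to 202). Without control library 2, Hba-a2 had 77.2 (26.2 to 376), and Eps8l2, with no control count left, had a lower 95% limit of 12.5. Without control library 3, the ratios were 28.1 (14.1 to 65.6) for Hba-a2, 67.1 (11.7 to 2680) for Sorcs1, 21.6 (5.72 to 183) for Csn2 and 15.4 (5.03 to 76.8) for Eps8l2. Of the 10 largest falls, 7 were in clustered histone genes. Hist1h1a fell from 99 counts to 6, 14.4-fold (6.4 to 40.3), Hist1h4d fell 12.3-fold and Hist1h2ag 10.9-fold. Hist1h2bk, Hist1h1b, Hist1h2bj and Hist1h3b fell 8.17-, 7.24-, 7.22- and 5.58-fold. The fall of Hist1h1a was 27.6-fold (7.43 to 231) and that of Hist1h2bj 12.2-fold without inhibitor library 1, and those of Hist1h2ag and Hist1h1b were 22.2- and 10.8-fold without inhibitor library 2. Copies of these histone genes are near-identical, so their counts are uncertain. Over the 35 clustered histone genes tested, a group chosen after its values were seen, 21 were lower, 5 higher and 9 did not pass, with a median of -1.36. Transcripts of clustered histone genes mostly lack poly(A) tails, so their counts from an mRNA kit also depend on how RNA was selected, and Rn45s counts were higher in every control than in every inhibitor library. The mean level of the histone genes, centred over the libraries, was 0.57, 0.45 and 0.61 in control libraries 1 to 3, with 20039, 3667 and 61656 Rn45s counts, and -0.58 to -0.50 in the inhibitor libraries, with 1784 to 3145. The other large falls were in Ccr9, a chemokine receptor of plasmacytoid dendritic cells and thymus-homing cells (chromosome 9, 123767211 to 123783457), in Fpr2, a formyl peptide receptor, and in the coagulation factor gene F7. Ccr9 went from 66.9 ± 14 to 9.80 ± 1.61 CPM, Fpr2 fell 7.15-fold (4.31 to 12.6) and F7 5.36-fold (4.11 to 7.09).

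**Figure D2:**
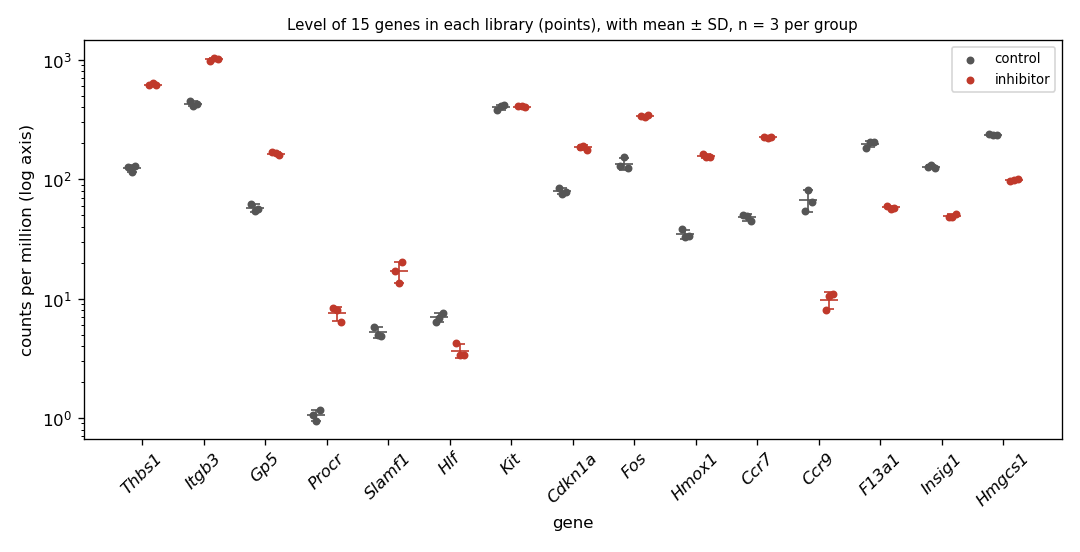
CPM (log axis) of 15 genes in each control and inhibitor library, with 1 point per library and bars for the mean ± SD of 3 libraries. The groups do not overlap for the genes shown except Kit, with mean levels of 401.9 and 406.2.

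Genes of the megakaryocyte lineage showed the broadest rise. Of the 34 megakaryocyte and platelet genes tested, 32 were higher and 2 lower (32 and 2 adjusted over the list alone), with a median change of 1.13 (camera adjusted p = 4.81e-55, and 0.015 with an estimated correlation). Besides Thbs1, the thrombin receptor genes F2r and F2rl2 rose by 1.64 ± 0.05 and 1.56 ± 0.06, Gp5, a subunit of the platelet receptor for von Willebrand factor, by 1.51 ± 0.06, and Vwf by 1.16 ± 0.06. The members that fell, chosen after their values were seen, were the transcription factor genes Gata2 (-0.36 ± 0.08) and Fli1 (-0.19 ± 0.06). The list shares 12 of its members with other lists. Of 41 HSC ageing genes tested, 29 were higher, 2 lower and 10 did not pass (30 and 2 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 1.08e-16, and 0.015 with an estimated correlation). Examples were Itgb3, the platelet integrin beta 3 chain (1.23 ± 0.06), the platelet protein multimerin gene Mmrn1 (1.46 ± 0.07) and the retinaldehyde dehydrogenase gene Aldh1a1 (2.80 ± 0.15). Without the 11 members shared with the megakaryocyte and immediate early lists, a choice made after seeing the data, 19 of the remaining 30 were higher and 2 lower, with a median of 0.63 (camera adjusted p = 2.21e-06, and 0.0412 with an estimated correlation).

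The HSC genes moved both ways. Of 44 tested, 20 were higher, 9 lower and 15 did not pass (20 and 11 adjusted over the list alone), with a median of 0.17, higher by camera (adjusted p = 1.69e-05, but adjusted p = 0.0654 with an estimated correlation). The median was 0.30 with a stricter filter on low counts and 0.31 without control libraries 1 and 3. Control means were low for Procr, Mecom, Slamf1 and Hlf (1.06, 0.64, 5.22 and 6.95 CPM). They were 401.9 CPM for Kit, 362.8 for Cd34 and 191.3 for Flt3, and 2243 CPM for the myeloid gene Lyz2. What share of the sorted cells were HSCs was not measured, so changes in the HSC and ageing lists need not come from HSCs. Procr, the endothelial protein C receptor used to sort HSCs (chromosome 2, 155751125 to 155755478), rose 7.08-fold, from 1.06 ± 0.11 to 7.55 ± 1.02 CPM. Slamf1, which encodes CD150, rose by 1.70 ± 0.16, Vldlr by 1.32 ± 0.07 and Txnip, a thioredoxin inhibitor, by 1.24 ± 0.05. The stem cell transcription factor gene Hlf fell (-0.92 ± 0.17). The change of Kit was 0.02 ± 0.06 and that of Mecom -0.70 ± 0.48, neither past the threshold. Kit was at -0.03 without control library 1 and Mecom at -1.10 and -0.45 without inhibitor libraries 1 and 3, again not past it. Cd34 (0.10 ± 0.06) and Flt3 (0.11 ± 0.06) did not pass either. Cd34 passed without control library 1 (0.11, adjusted p = 0.0325 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, range over its alternatives 0.0309 to 0.421). Flt3 passed without control library 2 (0.19, adjusted p = 0.0175 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, range over its alternatives 0.0175 to 0.745). Immediate early genes, which also respond to cell dissociation, rose beside these groups. Of 33 immediate early and dissociation genes tested, 21 were higher, 2 lower and 10 did not pass (21 and 2 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 1.57e-10, but adjusted p = 0.077 with an estimated correlation). Fos rose by 1.33 ± 0.07, Fosb by 1.33 ± 0.09 and the phosphatase gene Dusp1 by 1.96 ± 0.11. The heat shock gene Hspa1b, near-identical to Hspa1a and so uncertain, rose by 1.87 ± 0.10.

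Cell cycle genes were lower and genes of the p53 response higher. Of 55 G1/S and DNA replication genes tested, 38 were lower, 2 higher and 15 did not pass (41 and 2 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 4.17e-08, and 0.0171 with an estimated correlation). The replication licensing gene Cdc6 (-0.59 ± 0.06), the uracil glycosylase gene Ung (-0.77 ± 0.09), Uhrf1 (-0.48 ± 0.06) and Cdca7 (-0.46 ± 0.05) fell. Among 56 G2/M and mitosis genes, 21 were lower, 2 higher and 33 did not pass (21 and 2 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.00288, but adjusted p = 0.308 with an estimated correlation). Their median was -0.19 without control libraries 1 and 3, a setting chosen after seeing the data. The kinase gene Aurkb (-0.39 ± 0.06), Cks1b (-0.47 ± 0.06) and H2afx (-0.57 ± 0.07) fell and Psrc1, which the p53 list also holds, rose (0.67 ± 0.10). Of 39 p53 response genes tested, 20 were higher, 4 lower and 15 did not pass (21 and 4 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 1.84e-07, and 0.0202 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090979 to 29100722), rose 2.31-fold, from 79.9 ± 4.85 to 184.8 ± 7.37 CPM. Trp53inp1 rose by 1.41 ± 0.06, Zmat3 by 1.14 ± 0.08 and Ccng1 by 1.04 ± 0.06. Of 37 quiescence genes tested, 21 were higher, 3 lower and 13 did not pass (22 and 5 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 4.91e-05, but adjusted p = 0.112 with an estimated correlation). Examples besides Cdkn1a were Egr1 (1.27 ± 0.08), which is also an immediate early gene, and the antiproliferative gene Btg1 (0.66 ± 0.06).

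Genes of cholesterol synthesis were lower as a group. Of 25 tested, 24 fell (24 adjusted over the list alone), with a median of -0.90 (camera adjusted p = 3.24e-39, and 0.00435 with an estimated correlation). Besides Hmgcs1, Insig1, a sterol-responsive regulator of the pathway (chromosome 5, 28071412 to 28078662), went from 127.1 ± 3.82 to 49.6 ± 1.62 CPM, a change of -1.36 ± 0.06. Cyp51, the lanosterol demethylase, fell by 1.24 ± 0.06 on the log2 scale. The remaining member of the 25 did not pass.

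Some antioxidant genes rose several-fold. Hmox1, haem oxygenase 1 (chromosome 8, 75093618 to 75100593), rose by 2.17 ± 0.07, from 34.7 ± 2.99 to 156.3 ± 5.02 CPM. Srxn1, sulfiredoxin, rose 3.99-fold, from 71.8 ± 5.78 to 286.8 ± 2.95 CPM. Gclm, a subunit of the first enzyme of glutathione synthesis, rose by 1.57 ± 0.06 and the cystine transporter gene Slc7a11 by 1.93 ± 0.11. Of 37 antioxidant genes tested, 17 were higher, 6 lower and 14 did not pass (17 and 7 adjusted over the list alone), with a median of 0.11 and a mean of 0.38 (camera adjusted p = 7.38e-07, but adjusted p = 0.231 with an estimated correlation). The median was 0.16 without control library 1, 0.05 without control library 3 and 0.06 without inhibitor library 2 or without Rn45s and the 50 most abundant genes, and the list passed each time. Without control libraries 1 and 3 the median was 0.19. Of 75 nuclear oxidative phosphorylation genes tested, 45 were lower and 30 did not pass (46 lower adjusted over the list alone), with a median of -0.28 (camera adjusted p = 9.35e-07, but adjusted p = 0.513 with an estimated correlation). Ndufa5 (-0.74 ± 0.10), Ndufb6 (-0.82 ± 0.12) and Ndufb10 (-0.62 ± 0.09) of respiratory complex I and Uqcrq of complex III (-0.60 ± 0.09) fell. The median was -0.17 after a correction for GC content and length, chosen after seeing the data (camera adjusted p = 0.00324), and the call was lost with fry (adjusted p = 0.0591, range over its alternatives 2.95e-09 to 0.513). The mean level of this list, centred over the libraries, was 0.39 in control library 1, 0.04 and 0.05 in the other controls and -0.16 to -0.15 in the inhibitor libraries. Of 76 ribosomal protein genes, 19 were lower, 3 higher and 54 did not pass (10 and 3 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0231, but adjusted p = 0.713 with an estimated correlation). Rpl39 (-0.31 ± 0.06), Rps24 (-0.26 ± 0.07) and Rpl31 (-0.28 ± 0.07, or -0.18 without control library 1) fell and Rps26 rose (0.28 ± 0.06). After the GC and length correction Rpl39 was at -0.16 and Rps26 at 0.42, and Rps24 was at -0.14 without control libraries 1 and 3. Ribosomal protein genes have many processed pseudogenes, which makes their counts uncertain. Without control library 1 the list had a median of -0.04 and no longer passed (camera adjusted p = 0.189, range over its alternatives 0.000674 to 0.881). Nor did it pass without control libraries 1 and 3 (0.25) or after the GC and length correction (0.881), both chosen after seeing the data.

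**Figure D3:**
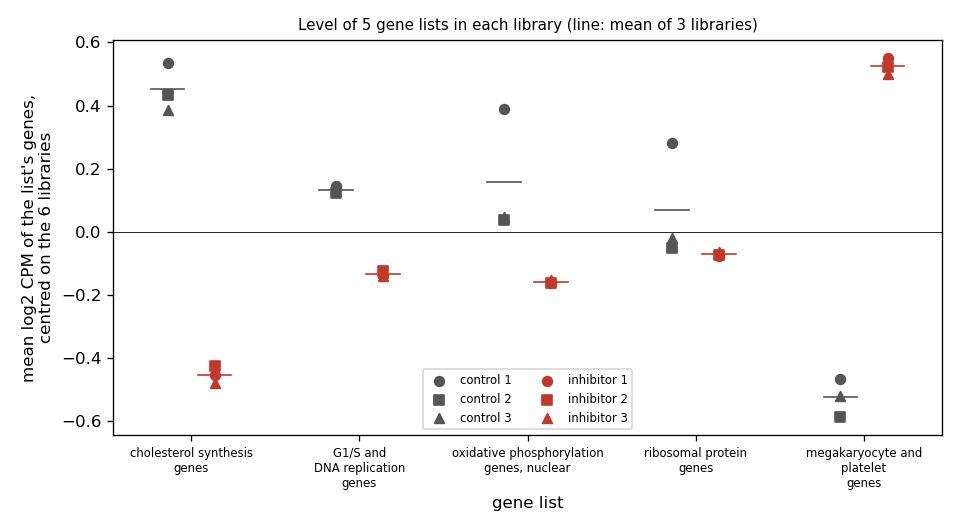
Mean log2 CPM of the genes of 5 lists in each library, centred on the 6 libraries, with 1 symbol per library and a line at each group's mean. Control library 1 stands above the other controls for the oxidative phosphorylation and ribosomal protein lists, while the groups are parted by 0.811 for cholesterol synthesis and 0.966 for megakaryocyte and platelet genes.

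Genes of mature myeloid cells moved in both directions. Of 28 monocyte and macrophage genes tested, 11 were lower, 9 higher and 8 did not pass (12 and 9 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.0404, lower, but adjusted p = 0.255 with an estimated correlation). F13a1, a coagulation factor subunit made by monocytes and megakaryocytes, fell (-1.77 ± 0.06), as did Lyz2 (-1.02 ± 0.05), Ly6c2 (-0.94 ± 0.06) and Fcgr3 (-0.73 ± 0.06). Counts of Lyz2 and Ly6c2 are uncertain because of the similar genes Lyz1 and Ly6c1. This call was lost without control library 2 (median -0.06, camera adjusted p = 0.0607), inhibitor library 1 (-0.08, 0.0577), 2 (-0.07, 0.0736) or 3 (-0.04, 0.0657), and without Rn45s and the 50 most abundant genes (-0.003, 0.152). The range over its alternatives was 0.000964 to 0.255, and the median was -0.12 without control library 1. Of 20 dendritic cell genes, 10 were higher, 6 lower and 4 did not pass (10 and 6 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.0359, but adjusted p = 0.493 with an estimated correlation). Ccr7, the receptor that guides mature dendritic cells to lymph nodes (chromosome 11, 99144199 to 99155077), rose 4.68-fold, from 48.1 ± 3.02 to 224.9 ± 2.90 CPM. The antigen presentation genes Cd74 (0.69 ± 0.06) and H2-Aa (0.60 ± 0.06) rose too, while Ccr9 fell (-2.78 ± 0.17). The call was lost without control library 1 (median 0.27, camera adjusted p = 0.134) and without control libraries 1 and 3 (0.18, 0.491). It was also lost without inhibitor library 1, where the median was higher (0.43, 0.0545), with a range over its alternatives of 0.00703 to 0.493. Of 22 erythroid genes, 13 were higher, 1 lower and 8 did not pass (13 and 2 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.000953, but adjusted p = 0.186 with an estimated correlation). Gata1 (1.00 ± 0.10) and Epb41 (0.64 ± 0.05) rose, and the beta globin gene Hbb-bs, near-identical to Hbb-bt, rose by 2.98 ± 0.29 from 0.44 ± 0.08 CPM. Of 36 marrow stromal, osteoblast and adipocyte genes, the filter on low counts left 10. Of these 10, 6 were higher, 2 lower and 2 did not pass (6 and 2 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 0.00404, but adjusted p = 0.456 with an estimated correlation). Lpl, lipoprotein lipase, rose by 1.35 ± 0.06, Spp1, osteopontin, by 1.13 ± 0.07 and Kitl, stem cell factor, by 1.54 ± 0.32 from 0.81 ± 0.28 CPM. This call was lost with no filter on low counts (median 0.91, camera adjusted p = 0.0646) and without control libraries 1 and 3 (0.55, 0.0559), with a range over its alternatives of 0.000748 to 0.456.

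The lists of interferon response, of TGF-beta and BMP and of adhesion genes were higher too. Of 49 type I interferon response genes tested, 21 were higher, 6 lower and 22 did not pass (24 and 7 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.0117, but adjusted p = 0.193 with an estimated correlation). The GTPase genes Igtp (1.21 ± 0.07), Gbp2 (1.68 ± 0.12) and Mx1 (1.57 ± 0.13) rose. The interferon call was lost without control libraries 1 and 3 (median 0.16, camera adjusted p = 0.0541, range over its alternatives 0.000749 to 0.193). Of 30 TGF-beta and BMP pathway genes, 18 were higher, 2 lower and 10 did not pass (20 and 4 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 1.33e-05, but adjusted p = 0.112 with an estimated correlation). Id2 (1.15 ± 0.08), Skil, a SMAD corepressor (1.05 ± 0.08), Ltbp1, which binds latent TGF-beta (0.88 ± 0.06), and the integrin gene Itgav (0.88 ± 0.06) rose. Of 38 adhesion and homing genes, 20 were higher, 6 lower and 12 did not pass (21 and 7 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.000202, but adjusted p = 0.153 with an estimated correlation). The tetraspanin gene Cd9 (1.13 ± 0.05) and the integrin gene Itga6 (0.67 ± 0.05) rose beside Itgb3, and 16 members of this list are held by others.

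Another 16 lists, candidate targets of miR-31-5p among them, did not pass by camera, though single members moved. Fry, which does not compare a list with other genes, called 8 of them. By fry, the adjusted p was 0.000146 for Hippo, 0.00703 for apoptosis, 0.00722 for NF-kB and 0.00812 for autophagy genes. It was 0.00888 for endothelial, 0.0345 for candidate target and 0.0392 for neutrophil genes, all these higher. Unfolded protein response genes were lower by fry (adjusted p = 0.0148). Of 42 NF-kB and inflammatory genes, 17 were higher, 13 lower and 12 did not pass (18 and 13 adjusted over the list alone, camera adjusted p = 0.283), with the chemokine gene Ccl5 at 3.02 ± 0.12 and Traf1 at 1.82 ± 0.10. Of 37 apoptosis genes, 11 were higher, 7 lower and 19 did not pass (12 and 7 adjusted over the list alone, camera adjusted p = 0.336), with the antiapoptotic gene Bcl2a1b, uncertain because it is near-identical to Bcl2a1d, at 2.13 ± 0.12. For unfolded protein response and heat shock genes the counts were 8 higher, 19 lower and 10 not passing of 37 (8 and 19 adjusted over the list alone, camera adjusted p = 0.15), with the phosphatase subunit gene Ppp1r15a at 1.22 ± 0.10 and the chaperone gene Calr at -0.49 ± 0.06. For glycolysis and hypoxia response genes they were 8, 14 and 24 of 46 (9 and 15 adjusted over the list alone, camera adjusted p = 0.167), with Pfkfb3 at 0.67 ± 0.05 and the monocarboxylate transporter gene Slc16a1 at -0.44 ± 0.06. For fatty acid oxidation and mitochondrial biogenesis genes they were 5, 8 and 24 of 37 (5 and 8 adjusted over the list alone, camera adjusted p = 0.52), with Ppargc1b at -0.57 ± 0.09 and Pparg at 0.72 ± 0.14. For autophagy and lysosome genes they were 11, 6 and 24 of 41 (11 and 6 adjusted over the list alone, camera adjusted p = 0.25), with the cathepsin genes Ctsd and Ctsl at 0.84 ± 0.06 and 1.06 ± 0.07. In the Wnt list they were 5, 4 and 17 of 26 (5 and 4 adjusted over the list alone, camera adjusted p = 0.996), with Myc at -0.66 ± 0.06 and Tcf7 at 1.56 ± 0.13. In the Notch list they were 3, 6 and 12 of 21 (3 and 6 adjusted over the list alone, camera adjusted p = 0.663), with the ligand gene Jag1 at 1.17 ± 0.14 and the protease gene Adam10 at 0.37 ± 0.05. In the Hippo list 6 of 19 were higher and 13 did not pass (6 adjusted over the list alone, camera adjusted p = 0.284), with Mob1b at 0.76 ± 0.07 and Yap1 at 2.61 ± 0.34. Of 46 epigenetic regulators, 8 were higher, 10 lower and 28 did not pass (8 and 10 adjusted over the list alone, camera adjusted p = 0.764), with the demethylase gene Kdm5b at 0.63 ± 0.07.

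Markers of other blood and vessel cells made up the rest of these lists. The filter on low counts left 14 of 28 listed B cell genes, 17 of 35 T and NK cell genes and 18 of 27 endothelial genes. Of 24 neutrophil and granule genes, 9 were higher, 10 lower and 5 did not pass (11 and 10 adjusted over the list alone, camera adjusted p = 0.284), with the calprotectin genes S100a8 and S100a9 at 1.62 ± 0.06 and 1.63 ± 0.08. Of 18 mast cell, basophil and eosinophil genes, 5 were higher, 5 lower and 8 did not pass (6 and 5 adjusted over the list alone, camera adjusted p = 0.403), with the protease genes Gzmb at -2.27 ± 0.11 and Mcpt4 at 0.61 ± 0.05. Of 14 B cell genes, 3 were higher, 5 lower and 6 did not pass (3 and 6 adjusted over the list alone, camera adjusted p = 0.52), with Spib at -0.93 ± 0.09 and the interleukin 7 receptor gene Il7r at 1.17 ± 0.12. Of 17 T cell and NK cell genes, 3 were higher, 8 lower and 6 did not pass (3 and 9 adjusted over the list alone, camera adjusted p = 0.185). This list passed as lower without control library 1 (camera adjusted p = 0.0415, range over its alternatives 0.0159 to 0.513). Of 18 endothelial genes, 8 were higher, 3 lower and 7 did not pass (9 and 3 adjusted over the list alone, camera adjusted p = 0.18), with the scavenger receptor gene Stab1 at -1.15 ± 0.08. The median, mean and camera direction differed in sign for the unfolded protein response, fatty acid oxidation, Wnt, mast cell and B cell lists.

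Genes proposed as targets of miR-31-5p did not differ from the other genes as a group by camera. The inhibitor was given before transplantation and the cells were sorted later. The counts measure neither miR-31-5p nor any inhibitor left in the sorted cells. They therefore cannot tell whether the inhibitor released these targets when it was given. Of 38 candidate targets tested, 10 were higher, 2 lower and 26 did not pass (9 and 2 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.52), or -0.01 without control library 1. Fry, which asks whether the genes move one way on balance and does not compare them with other genes, gave an adjusted p = 0.0345 (range over the list's alternatives 0.0345 to 0.993). Map3k14, the NF-kB-inducing kinase, rose by 0.71 ± 0.08 and Spred1, an inhibitor of Ras signalling, by 0.44 ± 0.06. Hif1an, the inhibitor of the hypoxia-inducible factor (chromosome 19, 44562854 to 44576274), had 63.7 ± 2.66 and 56.5 ± 3.54 CPM and a change of -0.18 ± 0.07 (adjusted p = 0.0516 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It passed as lower without control library 1 (-0.21, adjusted p = 0.00653 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with no filter on low counts (0.0499), after thinning (0.0396) and after the GC and length correction (0.00134), with a range over its alternatives of 0.00134 to 0.227. Lats2 (-0.12 ± 0.06) passed as lower without control library 1 (-0.16, adjusted p = 0.0363) and after the GC and length correction (0.026), range over its alternatives 0.026 to 0.438, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Satb1 (0.09 ± 0.07) and Dicer1 (0.05 ± 0.07) did not pass, although Dicer1 was at -0.11 and past the threshold after the GC and length correction, and at -0.03 without control library 1. Satb1 was at -0.01 after the correction. Rhobtb1 (-0.49 ± 0.16) was lower. Its call was lost, with a change close to this one, without control library 3 (-0.45, adjusted p = 0.0671), inhibitor library 2 (-0.46, 0.0703) or inhibitor library 3 (-0.45, 0.0711), and also without control libraries 1 and 3 (-0.24, 0.467), range over its alternatives 0.00787 to 0.467, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

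Transcripts with a seed match gave a like picture, with the same limit. Of 12330 tested genes with an annotated 3′ UTR, 1706 held the 8mer TCTTGCCA or the 7mer TCTTGCC and 10624 held neither. Their median log2 changes were 0.017 and -0.015, a difference of 0.032 (bootstrap 95% interval 0.014 to 0.051 over genes, which are not independent), and camera found no difference past the threshold (n = 1706 genes, p = 0.43). For the 536 genes with an 8mer the difference was 0.018 (n = 536 genes, camera p = 0.503). Of the genes with a site, 24.4% were higher and 18.9% lower, against 20.2% and 21% of the others. Genes with a site had longer 3′ UTRs (median 2530 against 1212 bases), and change correlated with 3′ UTR length across genes (Spearman's rho 0.175, over genes that are not independent replicates). Of 55 heptamers with the same letters in another order and a like number of genes, 41 had a difference at least as high, in a range of 0.017 to 0.063. The difference was 0.010 without control library 1, 0.008 without control libraries 1 and 3 and -0.008 after the GC and length correction (n = 1706 genes, camera p = 0.778, range over its alternatives 0.32 to 0.778).

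**Figure D4:**
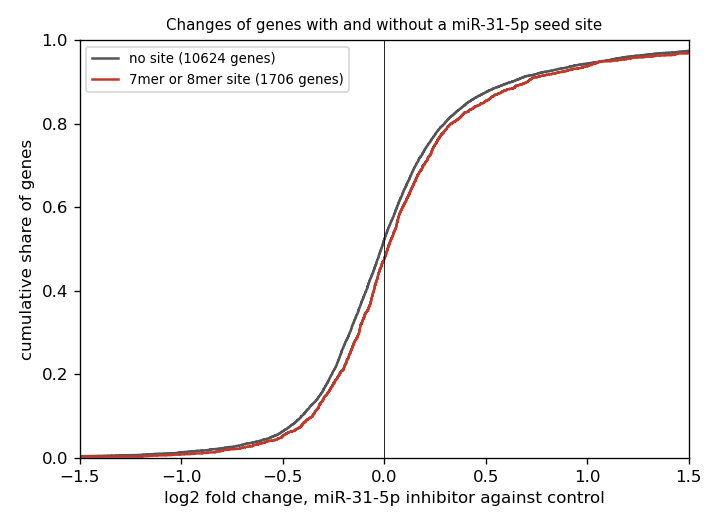
Cumulative share of genes (vertical axis) by log2 change, inhibitor against control (horizontal axis), for 1706 genes with a miR-31-5p seed site in the 3′ UTR and 10624 genes without one. The curve of genes with a site lies to the right by 0.032 at the median.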

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

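The correction for GC content and length, thinning, the setting without Rn45s and the 50 most abundant genes, and the setting without control libraries 1 and 3 were chosen after seeing the data. The number of genes past the threshold was 5259, and 853 (697 higher, 156 lower) with a log2 change of at least 1, by construction. It lay between 4058 and 5692 when 1 library was left out (2181 to 2849 higher, 1877 to 2843 lower), and was 5240 with RLE factors, 5519 without a filter, 5164 with a stricter one, 4790 with DESeq2, 5208 with limma-voom and 5952 after the GC and length correction. Without control libraries 1 and 3 it was 4045, where the lone control was assumed to vary like the others. With the replicate number as a block (replicate block) it was 5673, although the numbers do not pair the libraries, and the dendritic cell list no longer passed (camera adjusted p = 0.157, range over its alternatives 0.00703 to 0.493), while Hif1an passed as lower (-0.18, adjusted p = 0.0384 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, range over its alternatives 0.00134 to 0.227). Lists past the threshold numbered 19, 17 to 19 with 1 library left out, 25 with fry and 5 with an estimated correlation. An estimated correlation widens the variance of lists whose genes move together, but that alone does not account for the lower number. The HSC list, with an estimated correlation of 0.012 against the preset 0.01, went from a camera adjusted p of 1.69e-05 to 0.0654. The cholesterol synthesis list, at 0.001, went from 3.24e-39 to 0.00435. The seed site difference ranged from 0.010 to 0.039 with 1 library left out. After the GC and length correction, camera's direction for the ribosomal protein list turned to up, with a median still below 0, at -0.001 (adjusted p = 0.881, range over its alternatives 0.000674 to 0.881). Dicer1 was at -0.113 and past the threshold after it (adjusted p = 0.041 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, range over its alternatives 0.041 to 0.868). For Dicer1 the cause was not tested. Of the other comparisons of a named gene with its value under an alternative, 2034 stayed on their side of the threshold, 11 gained a call and 9 lost it, and for lists these numbers were 522, 10 and 30. Where the result had passed and still did, the sign was kept in all 1919 for genes and all 276 for lists. Where it passed in neither, the sign changed in 8 of 115 for genes (Satb1, Dicer1, Kit and Flt3) and, by the median, in 21 of 246 for lists (candidate targets, fatty acid oxidation, Wnt, epigenetic regulators and B cell genes). Fewer counts left wider limits: 3 counts were 0.141 CPM in the deepest and 0.178 CPM in the shallowest library.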

Other observations

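The tests of LXR targets, of mature and plasmacytoid dendritic cell genes and of NRF2 targets used lists drawn up after the patterns were seen, and the tests of GC content for ribosomal protein genes and of a lower share of other cells were also chosen only after the result was seen, as were thinning, leaving out Rn45s and abundant genes, and the GC and length correction. The fall of cholesterol synthesis genes, with the rise of Abcg1 (1.81), may reflect a higher activity of LXR, a sensor of oxidised sterols. Of 12 LXR target genes other than Abcg1, 9 were higher and 1, Scd2 (-0.54), lower, and camera gave an adjusted p = 0.000111 (0.0286 with an estimated correlation), with 3 of the 12 held by other lists. The rise of Ccr7 may belong to a programme of mature dendritic cells. Of 28 genes of that programme, 21 were higher and 1, Ebi3 (-0.66), lower (camera adjusted p = 1.16e-13, and 0.00595 with an estimated correlation), among them Slco5a1 (2.44), Serpinb9 (1.69) and Cd40 (1.47), with 3 of the 28 held by other lists. The rise of antioxidant genes could come from the transcription factor NRF2. Of 27 NRF2 targets outside the antioxidant list, 14 were higher and 3 lower (camera adjusted p = 3.14e-05), among them Akr1b8 (2.23) and Me1 (1.83), but the estimated correlation gave an adjusted p = 0.0875, which leaves this open. The fall of Ccr9 may reflect a lower share or activity of plasmacytoid dendritic cells, of whose 24 genes (9 held by other lists) 12 were lower and 2 higher (camera adjusted p = 0.00126), with Tlr7 at -0.90, Spib at -0.93 and Ly6d at -0.83. The 2 higher members were Atp1b1 (1.11) and Irf8 (0.24). The other 10 did not pass, among them Tcf4 (0.08), Runx2 (0.15) and Irf7 (-0.11). This explanation too stays open, since the camera adjusted p = 0.0922 with an estimated correlation. The genes printed here were chosen after their values were seen.

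The first pattern weighed was the number of genes past the threshold, 5259. A difference in library size is argued against by the 5146 genes that passed after every library was thinned to the smallest total. Without Rn45s and the 50 most abundant genes 5245 passed, so the number did not rest on the counts of those genes themselves. Rn45s held only 0.011 to 0.29% of the counts, and leaving genes out cannot undo a difference in RNA selection that acts on others. Such a difference was not tested. The 6 libraries can be parted into 3 and 3 in 10 ways, which cannot give a share under 0.05. The real one, 1 of the 10, gave 5259 genes and the highest of the others 0, with 60 to 171 at an unadjusted p under 0.05 by edgeR, and 0 at an adjusted p under 0.05 by limma-voom. In every other way, each side held control and inhibitor libraries. Any difference between the groups then counted as spread within a side, which lowers the number of genes that pass. The contrast of 5259 with 0 therefore cannot tell how many genes would pass without a group difference, and no conclusion is drawn from it. The same limit holds for the lists and the seed sites below. The treatment and any batch that follows it remain possible explanations. The labels give no batch. For the lists, 1 of the 10 ways gave 19 or more and the highest of the others gave 16. For the seed sites, 9 of the 10 ways gave a camera p as small as the real 0.43, and the smallest of the others was 0.0582, and again 10 ways are too few for a share under 0.05.

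The second pattern was the fall of the oxidative phosphorylation and ribosomal protein lists. For the ribosomal protein list, a trend with GC content and transcript length could be the cause, since its median went from -0.144 to -0.001 with the correction. For the oxidative phosphorylation list the correction moved the median from -0.279 to -0.165 (camera adjusted p = 0.00324, range over its alternatives 2.95e-09 to 0.513), so the trend may be part of the cause. The list's uncorrected median lay at percentile 0 of 10000 random lists matched for GC content, length and level (their median -0.165, 95% of them -0.214 to -0.094). Those lists were drawn gene by gene, while the genes of this list moved together (estimated correlation 0.638). Their spread is therefore too narrow to decide whether the trend is the whole cause, and no conclusion is drawn from the percentile. Variation between libraries that the whole list shares stays open, because the gap between the nearest libraries of the groups, 0.188, was smaller than the range within the controls, 0.35, where control library 1 stood highest, and a difference due to the inhibitor stays open as well.

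The third pattern was the rise of megakaryocyte and platelet genes. A lower share of cells outside all the listed cell types would raise the genes of every listed type alike. That is argued against because the medians of the neutrophil, monocyte, mast cell, B cell and T cell lists all lay below that of the megakaryocyte list. The largest distance, of T cell and NK cell genes, was 1.403 ± 0.438 (log2), and the smallest, of neutrophil genes, 0.967 ± 0.253. The T cell and NK cell list also holds Ccr9 and Gzmb, which other lists hold, so its median need not come from T cells. These SEs treat genes as independent, which they are not. A lower share of some listed cells, such as monocytes or T cells, would lower their genes, so the test cannot decide on it. A higher share of megakaryocyte-lineage cells or platelets among the sorted cells stays open: of 13 megakaryocyte and platelet genes, 11 (a share of 0.846) lay within 0.5 of their median log2 change of 1.46, the exceptions being Ppbp (0.36) and Tubb1 (1.98), chosen after their values were seen. The abundant platelet genes went from 449.8 to 1183 CPM (Pf4) and from 261.7 to 334.7 CPM (Ppbp), and the GFP sort is the gate the labels name. Itga2b and Mmrn1 of the 13 are also in the HSC and ageing lists, so a shift of the HSCs themselves towards the megakaryocyte lineage, which was not tested, could give the same values.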
